A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

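The series holds 24 samples of Saccharomyces cerevisiae strain CEN.PK, 12 RNA-seq and 12 MNase-seq, from the same 12 sampled times. The MNase-seq samples were not analysed here. Per the labels' protocols, RNA was extracted with hot phenol and made into libraries with an NEBNext Ultra RNA kit. That kit does not mark the strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Bowtie2 and genome build R64 are named in the submitters' processing notes. The read counter and the gene annotation are not given in the sources used here.

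The authors deposited 1 table of signal per gene and library, headed RKPM in the file, and a table with each gene divided by its highest library. Columns are numbered 1 to 12 and were matched to the RNA-seq samples by the number in the sample titles. The deposited values were checked against gene lengths and were found to be per-base coverage per kilobase, scaled to library size. A value times gene length in kilobases summed to 41500000 to 44800000 per library, far above the sum that RPKM values can reach. Low values lay closer to whole multiples of 1 base than random ones, by the step score below. After rounding to the nearest base, 299 of 1649 low values fell at 50, 100, 150 or 200 bases. The deposited signal was therefore divided by the read length of 50 bases, as estimated from those pile-ups, and is called RPKM here. This step rests on the values alone, since no source used here states it. The design had been written for RPKM, and the unscaled values are among the alternatives. The second deposited table holds a fraction between 0 and 1 of the gene's maximum, and it was used only in 1 alternative. It equalled the first table divided by the gene maximum to within 2.22e-16 for all 6562 genes. No scaling between libraries other than to library size was found in the deposited signal, and none was added in the main analysis. In the tables used here, 4 lines were empty.

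Depth was read from the steps between low values of genes of known length. It came to about 4370000 to 5940000 reads per library, and the pile-ups gave 4420000 to 6200000. The step score was 0.569 to 0.852, against at most 0.536 for the highest of 20 random sets of values in any library. The score of 0 min was the lowest and its random maximum was 0.499. With these depths, 1 read in a gene of 1 kilobase equals 0.168 to 0.229 RPKM. Between 30 and 61 genes per library are listed at 0. These depths are estimates, so no counting interval was made from them.

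Of the 6562 genes, 5891 were matched by systematic name to an annotation of build R64, from which symbols, coordinates, lengths and neighbours were taken, and 671 were not matched. Of those matched, 180 overlap another gene.

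Genes with a mean of at least 1 RPKM over the libraries were tested, 6493 in all. A natural cubic spline in minutes with 4 degrees of freedom was fitted to log2(RPKM + 1), and its F-test was moderated in limma 3.58.1 (R 4.3.3) with a trend in the mean. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fit leaves 7 residual degrees of freedom. Fold changes on the log2(RPKM + 1) scale understate those of low genes. The fitted range is the highest minus the lowest fitted value at the sampled times, with its standard error from limma, and 2-fold means a range of at least 1. The median residual SD was 0.371.

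Before the data were examined, 28 gene lists and 8 pairs of lists were fixed, with the design and most alternatives. A list needs at least 5 measured members, which 27 lists had. For each list the mean over members was tested by permutation of the time points with 100000 random orders, using the share of variance that the same spline explains, adjusted over lists. Pairs were tested in the same way on the difference of the means, adjusted over pairs. The range of a list is between its highest and lowest library, and the SD over members is that of this difference. The members said to be in that direction were higher in the first library than in the second. The share of genes varying by at least 2-fold was set against the other genes with Fisher's exact test, two-sided. Genes of a list are not independent.

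The genes named follow a rule fixed in advance. It takes the 2 widest fitted ranges of each list past the permutation test, among genes past the threshold with a mean of at least 10 RPKM. It adds the 10 widest ranges over all such genes with a symbol, and 11 genes chosen whatever their values. The last are the 3 genes highest and the 3 lowest across the step with the most genes moved. The rule gave 30 genes.

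The statistics were tested on simulated data with a noise SD of 0.169 on the log2 scale plus counting noise. That SD is below the median residual SD of the real fits, 0.371, so the rates apply to the simulated scatter and not to the larger residuals of real genes. Smooth courses of 2-fold were recovered for 73.1% of genes, 4-fold for 100% and 8-fold for 98.5%, with 14 false calls among 5846 genes. Pulses confined to 220 and 230 min were recovered for 0% at each of these sizes, with 4 and with 5 degrees of freedom, so a gene that does not pass may still have a narrow pulse. Of 200 lists without any course, 3 fell below an unadjusted permutation p of 0.05.

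Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 10 RPKM, median-ratio scaling, quantile normalization, 3 or 5 degrees of freedom, time point number in place of minutes, 2 harmonics of 260 min, leaving out overlapping genes, the median over members, the deposited fractions and leaving out each library. Each spline fit placed its knots, where the pieces of the curve join, at the quartiles of the times it used. Leaving out a library therefore moved the knots too. A call lost or gained in this way cannot be put down to that library's values alone. Other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.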

Results

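The series followed budding yeast (Saccharomyces cerevisiae, strain CEN.PK, grown in minimal medium) through the yeast metabolic cycle. In that cycle, dense cultures held under limited glucose pass together through repeated rounds of high and low oxygen consumption. RNA-seq and MNase-seq, which maps nucleosomes by digesting the DNA between them, were done at the same 12 time points, 0, 20, 60, 110, 140, 180, 200, 210, 220, 230, 240 and 260 min. The 12 RNA-seq libraries are described here, and the 12 MNase-seq samples were not analysed here. Each time point had 1 RNA-seq library, so no value has a replicate. Errors are the scatter of the libraries about a smooth curve in time, and p-values measure departure from a flat line against that scatter. They do not measure spread between cultures. Depth was estimated from the steps between low values, and it ran from about 4370000 reads at 20 min to 5940000 at 0 min. The median gene had a mean of 307 reads per library. The 10 most abundant genes took 5.74% of the signal at 240 min and 13.1% at 20 min.

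Ranges were ranked among genes past the threshold with a symbol and a mean of at least 10 RPKM. The widest fitted range among them belonged to NSR1 (YGR159C, chromosome VII, 806412 to 807656), a nucleolar protein of ribosomal RNA processing. It stood at 1689 RPKM at 220 min and 3.13 RPKM at 260 min. Its fitted range was 7.51 ± 0.98 (SE) on the log2(RPKM + 1) scale (limma, adjusted p = 0.00415). URA7 (YBL039C, chromosome II, 143989 to 145728), a CTP synthase, went from 452 RPKM at 220 min to 1.01 RPKM at 260 min (range 6.74 ± 1.08, adjusted p = 0.00439). GUA1 (YMR217W, chromosome XIII, 701790 to 703367), the GMP synthase, was at 1021 RPKM at 220 min and 4.31 RPKM at 20 min (range 5.96 ± 1.20, adjusted p = 0.0126). Of the 10 widest ranges among the genes ranked, 2 did not peak at 220 min. They belonged to RGI1 and RGI2, a pair of related genes induced in respiratory growth. RGI1 (YER067W, chromosome V, 292066 to 292551) was highest at 260 min, at 1504 RPKM, and lowest at 220 min, at 9.80 RPKM (range 5.95 ± 0.91, adjusted p = 0.00477). RGI2 (YIL057C, chromosome IX, 247902 to 248396) was highest at 20 min, at 5729 RPKM, and lowest at 230 min, at 16.8 RPKM (range 7.06 ± 1.55, adjusted p = 0.0498). The order of the ranges depended on the curve. With 5 degrees of freedom the fitted range was 8.39 for RGI2 and 7.92 for NSR1. SPG1, POX1 and ADY2, which did not pass in the main fit, then had ranges of 7.83, 7.63 and 7.57, against 7.40 for URA7. RGI2 passed with 5 degrees of freedom (limma adjusted p = 0.000627), but its call in the main fit lay at the threshold. That call was lost in several settings, among them quantile normalization (adjusted p = 0.0518), median-ratio scaling (0.051) and leaving out 200, 210, 220, 230 or 240 min (0.0657 to 0.345). URA7 and GUA1 lost theirs without 220 min (limma adjusted p of 0.0641 and 0.133), 230 min (0.0521 and 0.107) or 240 min (0.0535 and 0.0939), and GUA1 without 260 min (0.0546). With 3 degrees of freedom all 5 of these genes lost their calls (limma adjusted p of 0.101 for NSR1, 0.143 for URA7, 0.182 for GUA1, 0.253 for RGI1 and 0.335 for RGI2).

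The first question of the time course was which genes vary over it, and when they are highest. Of 6493 genes tested, 1343 (20.7%) varied at an adjusted p of 0.05, and 1342 of these did so by at least 2-fold. At an unadjusted p of 0.05 the count was 2651. Among those 1342, 583 had their highest library at 220 min, 206 at 230 min and 316 at 260 min. The lowest library was 260 min for 571 genes, 220 min for 249 and 20 min for 216. ACT1 (YFL039C), the actin gene, did not pass (range 0.54 ± 0.35, adjusted p = 0.594) and stayed between 825 and 1627 RPKM. The count depended on the degrees of freedom of the curve, with 145 genes at 3 and 2589 at 5. Changing them altered both the stiffness of the curve and the place of its knots, so neither is singled out. The count was 2657 with time point number in place of minutes. It also changed when single libraries were left out: it was 3309 without 0 min, 2798 without 20 min, 2097 without 60 min, 618 without 210 min, 282 without 220 min, 338 without 230 min, 277 without 240 min and 828 without 260 min. Leaving out a library also moved the knots of the spline. These counts therefore cannot separate the weight of a library's values from the change in the curve.

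**Figure D1:**
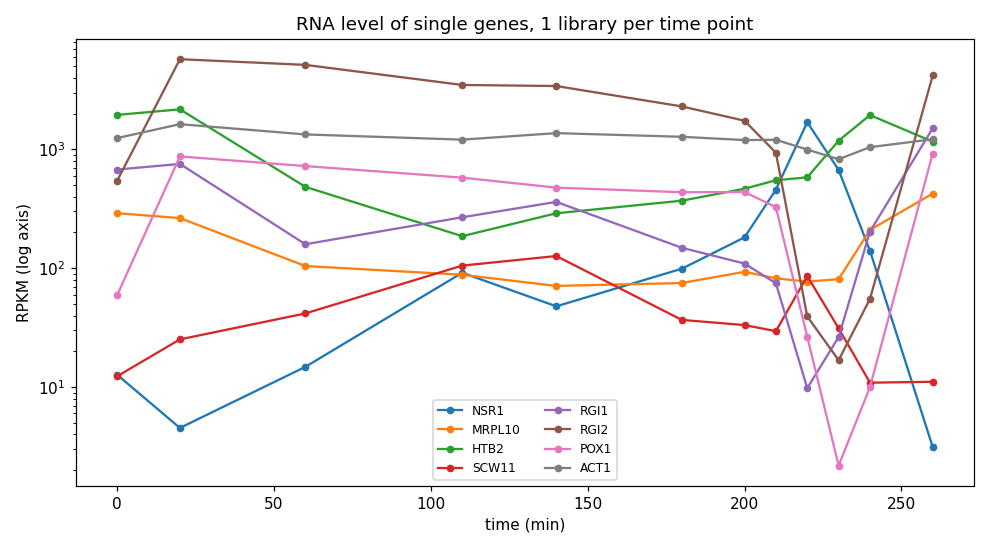
RNA level of 8 genes in RPKM (log axis) against time in minutes, 1 library per point. NSR1 reaches 1689 RPKM at 220 min and 3.13 RPKM at 260 min, while RGI1 and RGI2 have their lowest points at 220 and 230 min and ACT1 stays between 825 and 1627 RPKM.

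Cytosolic ribosome assembly was followed with 88 genes of ribosome biogenesis, fixed before the data were examined. All 88 varied, over all genes tested and when adjusted over the list alone. Their mean rose to a peak at 220 min and fell to its lowest level at 260 min, a range of 5.60 on the log2 scale (48.6-fold, SD over members 0.94), and all 88 members were higher at 220 than at 260 min. The highest library was 220 min for 78 members and 230 min for the other 10, and the lowest was 260 min for 77 and 20 min for 11. MAK16 (YAL025C, chromosome I, 100225 to 101145), needed for the large subunit, was at 335 RPKM at 220 min and 0.849 RPKM at 260 min (range 6.62 ± 0.94, adjusted p = 0.00422). UTP23 (YOR004W, chromosome XV, 333592 to 334356), of the small-subunit processome, had a range of 6.32 ± 0.78 (adjusted p = 0.00415). BRX1 (YOL077C, chromosome XV, 185848 to 186723), of the large subunit, had 6.11 ± 1.09 (adjusted p = 0.00899), and the helicase gene DBP3 (YGL078C, chromosome VII, 360288 to 361859) had 6.06 ± 1.04 (adjusted p = 0.00715). CGR1 (YGL029W, chromosome VII, 440063 to 440425), a nucleolar protein, was at 163 RPKM at 220 min and is listed at 0 at 260 min (adjusted p = 0.00464). These 5 genes lost their calls without 220 min (limma adjusted p of 0.0513 to 0.109), BRX1, CGR1 and DBP3 without 230 min (0.0547 to 0.0864), and BRX1 and DBP3 without 240 min (0.066 and 0.0656). All 5 also lost them with 3 degrees of freedom (limma adjusted p of 0.166 to 0.187). The mean profile passed the permutation test of the time order (adjusted p = 0.0227), and the list held more varying genes than the rest (Fisher's exact test, adjusted p = 1.48e-60). The permutation call was lost with 3 degrees of freedom (adjusted p = 0.226), with 2 harmonics (0.056) and with the deposited fractions (0.0924). It was also lost without the library at 200 min (permutation adjusted p = 0.0626), 210 (0.0661), 220 (0.153), 230 (0.146), 240 (0.109) or 260 min (0.0769). With 3 degrees of freedom 0 of the 88 varied, and the call on the share was lost too.

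Cytosolic ribosomal protein genes were highest at 230 min and lowest at 260 min, with a range of 3.25 (9.50-fold, SD over members 0.70) and all 138 measured members higher at 230 than at 260 min. Of these, 25 varied over all genes and 105 when adjusted over the list alone, and the mean profile did not pass (permutation adjusted p = 0.137). RPL17B (YJL177W), of the large subunit, stood at 1366 RPKM at 230 min and 88.5 RPKM at 260 min and did not pass (range 2.93 ± 0.89, adjusted p = 0.0894), but did with 5 degrees of freedom (limma adjusted p = 0.00899). Translation factors followed a like course, highest at 230 and lowest at 260 min (range 2.27, 4.82-fold), with 35 of 37 members higher at 230 min. In that list 21 genes varied over all genes and 30 adjusted over the list alone, a larger share than in the rest (Fisher's exact test, adjusted p = 1.35e-05), while the mean profile missed the threshold (permutation adjusted p = 0.0693). Aminoacyl-tRNA synthetases, which charge transfer RNA, were highest at 230 and lowest at 20 min (range 2.65, 6.27-fold), all 18 in that direction. There 7 varied over all genes and 15 adjusted over the list alone (permutation adjusted p of the mean = 0.116). With 5 degrees of freedom all 3 of these lists passed the permutation test, with adjusted p of 0.0272 for ribosomal proteins, 0.0272 for translation factors and 0.0279 for the synthetases. The varying ribosomal protein genes then numbered 135. All 3 also passed without 0 min (permutation adjusted p of 0.00081 to 0.00292) and without 20 min (0.00864 to 0.0189). Translation factors passed with median-ratio scaling (permutation adjusted p = 0.0475), quantile normalization (0.0453), time point number (0.0304) and without 60 min (0.0422). The larger share of varying translation factors was lost with 3 degrees of freedom, with 2 harmonics and without 210, 220, 230, 240 or 260 min (exact test, adjusted p of 0.505 to 1). Many ribosomal protein genes exist as near-identical pairs, between which the deposited values may have split reads.

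Amino acid synthesis genes outside the sulfur pathway were highest at 220 min and lowest at 20 min (range 2.21, 4.63-fold, 60 of 64 members higher at 220 min). Of these 13 varied over all genes and 17 adjusted over the list alone, and the mean did not pass (permutation adjusted p = 0.139). Sulfur assimilation and methionine genes had the same extremes with a range of 3.13 (8.74-fold) and all 33 members in that direction. There 5 varied over all genes and 16 adjusted over the list alone (permutation adjusted p of the mean = 0.138). The amino acid and sulfur means passed without 0 min (permutation adjusted p of 0.000877 and 0.00607) and without 20 min (0.0135 and 0.0131). GCN4 (YEL009C), the transcription activator of amino acid synthesis genes, lay between 1580 RPKM at 260 min and 2977 RPKM at 140 min and did not pass (range 0.78 ± 0.44, adjusted p = 0.580).

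Mitochondrial ribosomal protein genes ran on a different schedule from their cytosolic counterparts. Their mean rose to its highest level at 260 min from its lowest at 140 min, a range of 2.21 (4.63-fold, SD over members 0.41), and all 70 members were higher at 260 than at 140 min. Of the 70, 68 varied over all genes and 69 adjusted over the list alone, and 65 had their highest library at 260 min. MRPL7 (YDR237W, chromosome IV, 936615 to 937493), of the large mitochondrial subunit, rose from 35.6 RPKM at 140 min to 326 RPKM at 260 min (range 3.06 ± 0.35, adjusted p = 0.00415). RSM26 (YJR101W, chromosome X, 618234 to 619034), of the small mitochondrial subunit, rose from 40.6 RPKM at 110 min to 288 RPKM at 260 min (range 3.01 ± 0.36, adjusted p = 0.00415). MRPL10 (YNL284C, chromosome XIV, 103134 to 104102) rose from 70.9 RPKM at 140 min to 424 RPKM at 260 min (range 2.52 ± 0.35, adjusted p = 0.00415). The mean profile passed the permutation test (adjusted p = 0.0208), and the share of varying genes exceeded the rest (Fisher's exact test, adjusted p = 1.47e-43). That call was lost without 200 min (permutation adjusted p = 0.0626), 210 min (0.0661), 240 min (0.0626) or 260 min (0.0769).

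Genes of the respiratory chain and ATP synthase were highest at 0 min and lowest at 220 min (range 1.80, 3.49-fold, all 37 members in that direction). None of the 37 passed the gene test (limma), over all genes or adjusted over the list alone. That is fewer than in the rest (Fisher's exact test, adjusted p = 0.00142), and the mean did not pass (permutation adjusted p = 0.426). The range of the mean was still wider than in all of 10000 random lists of like size and mean expression. Members that move together give such a range whatever the time order, so this is a description and not a test. Cytosolic ribosomal proteins, translation factors and glycogen and trehalose genes reached it too. A sharp dip can be missed by this curve, as the simulated pulses were, so the deficit does not show steady RNA. The deficit was lost with median-ratio scaling (4 of 37 varying, exact test, adjusted p = 0.0674), with 3 degrees of freedom (1) and without 210, 220, 230 or 240 min (0.0899 to 0.689). The tricarboxylic acid cycle had the same extremes (range 2.56, 5.88-fold, all 12 members). Again 0 genes varied over all genes and 0 adjusted over the list alone, and the permutation adjusted p of the mean was 0.136. The range of the mean was wider than in 99.68% of the random lists. This list passed with time point number in place of minutes (permutation adjusted p = 0.0264) and with median-ratio scaling (0.0284). The transcripts of the mitochondrial genome were fixed as a further list of 8 genes, of which 0 were measured, so it was not tested.

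**Figure D2:**
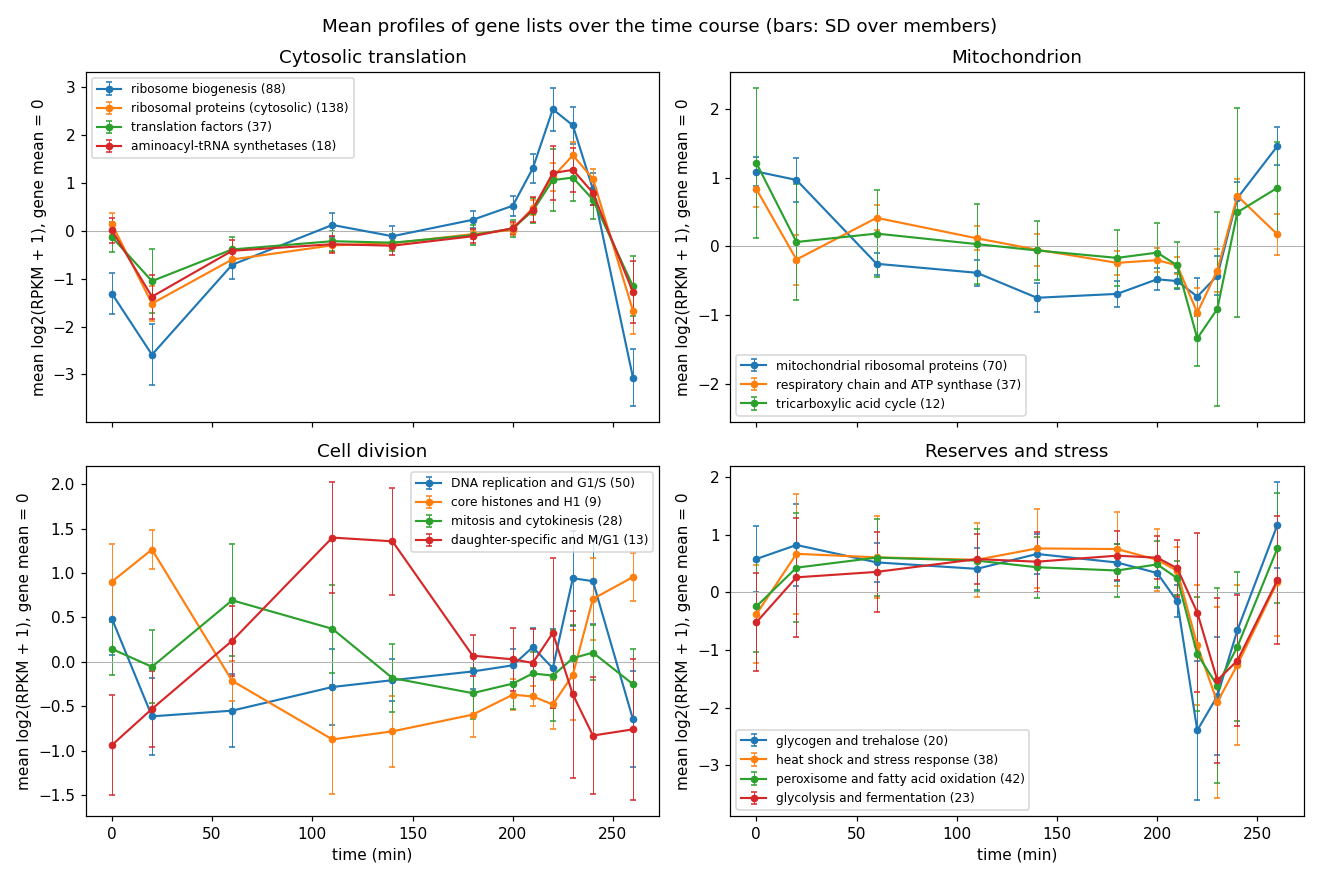
Mean log2(RPKM + 1) of 15 gene lists with each gene's own mean set to 0, against time in minutes, with members in brackets and bars of 1 SD over members. Ribosome biogenesis spans 5.60 log2 units between 220 and 260 min, whereas mitochondrial ribosomal proteins are highest at 260 min.

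Among cell division genes, the means of 2 lists passed the permutation test, the core and linker histone genes and the daughter-specific genes; the difference in timing between them was not tested. Histone genes rose to their highest mean at 20 min and were lowest at 110 min (range 2.13, 4.39-fold, SD over members 0.79), and all 9 members were higher at 20 min. Of these 7 varied over all genes and 8 adjusted over the list alone. HTB2 (YBL002W, chromosome II, 236492 to 236887) went from 2170 RPKM at 20 min to 186 RPKM at 110 min (range 3.51 ± 0.54, adjusted p = 0.00748). HTA2 (YBL003C, chromosome II, 235394 to 235792) went from 1468 RPKM at 0 min to 184 RPKM at 110 min (range 3.12 ± 0.38, adjusted p = 0.00415). HTA1 (YDR225W), a near-identical copy of HTA2 with which it may share reads, did not pass (range 1.22 ± 0.55, adjusted p = 0.233) and had 3570 RPKM at 20 min and 853 RPKM at 230 min. The histone mean passed the permutation test (adjusted p = 0.0227), as did the share of varying genes (Fisher's exact test, adjusted p = 0.00149). Daughter-specific genes, expressed after division in the new cell, were highest at 110 min and lowest at 0 min (range 2.33, 5.04-fold), with 12 of 13 members in that direction. There 9 varied over all genes and 13 adjusted over the list alone. The cell wall gene SCW11 (YGL028C, chromosome VII, 441281 to 442909) had 127 RPKM at 140 min and 10.9 RPKM at 240 min (range 3.29 ± 0.72, adjusted p = 0.0328). DSE4 (YNR067C, chromosome XIV, 755746 to 759099), a glucanase that separates daughter from mother, had 65.0 RPKM at 140 min and 5.77 RPKM at 0 min (range 3.21 ± 0.73, adjusted p = 0.0301). Quantile normalization ended both of these calls (adjusted p of 0.0609 for SCW11 and 0.0682 for DSE4), as did leaving out 110, 140, 210, 230, 240 or 260 min (0.053 to 0.114). SCW11 also lost its call with median-ratio scaling (adjusted p = 0.0514) and without 200 min (0.0532), and with 2 harmonics (0.0664). With 3 degrees of freedom both lost their calls (adjusted p of 0.0922 for SCW11 and 0.0673 for DSE4). The daughter-specific mean passed as well (permutation adjusted p = 0.0227), with more varying genes than the rest (Fisher's exact test, adjusted p = 0.00115). Both list calls were lost without the library at 110, 140, 200, 210, 230, 240 or 260 min, with permutation adjusted p between 0.0626 and 0.0993, and with the deposited fractions (0.0619 for histones and 0.0924 for daughter-specific genes). The daughter-specific call was lost with time point number and 5 degrees of freedom, a setting chosen after seeing the data (permutation adjusted p = 0.0712). The call on the share of varying histone genes was lost there (exact test, adjusted p = 0.119), with 5 degrees of freedom (0.0512), with time point number (0.0586) and without 110 (0.123) or 210 min (0.0899). That on the daughter-specific share was lost without 240 min (exact test, adjusted p = 0.0863).

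DNA replication genes were highest at 230 min and lowest at 260 min (range 1.59, 3.00-fold, 48 of 50 members in that direction), with 23 members highest at 230 min and 25 at 240 min. Only 3 varied over all genes and 0 adjusted over the list alone, and the mean did not pass (permutation adjusted p = 0.399). The range of the mean was still wider than in all of 10000 random lists of like size and mean expression, again a description and not a test. The share of varying genes was below the rest (Fisher's exact test, adjusted p = 0.0172), but with 5 degrees of freedom 19 of the 50 varied and the deficit was gone (0.919). It was also lost with 3 degrees of freedom, median-ratio scaling, 2 harmonics, time point number with 5 degrees of freedom and without 0, 220, 230, 240 or 260 min (exact test, adjusted p of 0.0541 to 1). CLN3 (YAL040C), a cyclin that promotes entry into the cell cycle, had 68.2 RPKM at 230 min and 10.9 RPKM at 260 min and did not pass (range 2.04 ± 0.60, adjusted p = 0.0764). With 5 degrees of freedom CLN3 passed (limma adjusted p = 0.00173). Genes of mitosis and cytokinesis were highest at 60 min and lowest at 180 min (range 1.04, 2.06-fold, 26 of 28 members). Of these 10 varied over all genes and 10 adjusted over the list alone, and the mean missed the threshold (permutation adjusted p = 0.0693). It passed with median-ratio scaling (permutation adjusted p = 0.00216), quantile normalization (0.00189), 2 harmonics (0.0495), the median over members (0.0367) and without 20 min (0.0241). Mating genes were highest at 230 and lowest at 20 min (range 1.61, 3.05-fold, 24 of 27 members), 3 varying over all genes and 3 adjusted over the list alone (permutation adjusted p of the mean = 0.274). Meiosis and sporulation genes had a range of 0.53 between 140 and 260 min (31 of 37 members), 4 varying over all genes and 2 adjusted over the list alone (permutation adjusted p = 0.138).

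Genes of storage carbohydrates, stress and fat use were lowest at 220 or 230 min, when ribosome biogenesis was high. Glycogen and trehalose genes were highest at 260 min and lowest at 220 min (range 3.56, 11.8-fold, SD over members 1.82, all 20 members). Of these 12 varied over all genes and 16 adjusted over the list alone, a larger share than in the rest (Fisher's exact test, adjusted p = 0.000934), while the mean missed the threshold (permutation adjusted p = 0.116). The mean of heat shock and stress genes was highest at 140 and lowest at 230 min (range 2.66, 6.33-fold, 36 of 38 members), 11 varying over all genes and 26 adjusted over the list alone (permutation adjusted p of the mean = 0.138). The high level was broad: with each gene's mean set to 0 it was 0.760 at 140 min, 0.749 at 180 min and 0.667 at 20 min. The highest library was 20 min for 15 members and 140 min for 3. CTT1 (YGR088W), the cytosolic catalase, fell from 333 RPKM at 60 min to 2.93 RPKM at 230 min (range 5.72 ± 1.23, adjusted p = 0.0483), a call lost with median-ratio scaling (0.0514), with a pseudocount of 0.1 (0.0538), with 3 degrees of freedom (0.244) and without 200, 210, 220, 230 or 240 min (0.0669 to 0.267). HSP12 (YFL014W), a small heat shock protein, had 34337 RPKM at 20 min and 266 RPKM at 240 min and did not pass (range 5.49 ± 1.66, adjusted p = 0.157). Peroxisome and fatty acid oxidation genes were highest at 260 and lowest at 230 min (range 2.38, 5.20-fold, 36 of 42 members). There 1 gene varied over all genes and 0 adjusted over the list alone, and the mean did not pass (permutation adjusted p = 0.175). That share was below the rest (Fisher's exact test, adjusted p = 0.00481), and with 5 degrees of freedom it was above it, at 29 of 42 (0.000405). It was above the rest without 0 min (28 of 42, exact test, adjusted p = 0.0421) and without 20 min (25 of 42, 0.0273) as well. With time point number 22 of 42 varied (exact test, adjusted p = 0.146), so no deficit is claimed for this list. POX1 (YGL205W), the acyl-CoA oxidase of fatty acid breakdown, had 922 RPKM at 260 min and 2.19 RPKM at 230 min and did not pass (range 6.02 ± 1.80, adjusted p = 0.144). With 5 degrees of freedom the means of all 3 lists passed, with permutation adjusted p of 0.0405 for glycogen and trehalose and 0.0272 for both stress and peroxisome. Glycogen and trehalose and stress passed with time point number (permutation adjusted p of 0.0231 and 0.0433) and without 0 min (0.0331 and 0.0334). Glycogen and trehalose also passed without 20 min (permutation adjusted p = 0.0366) and with the deposited fractions (0.042). The call on its share was lost with 3 degrees of freedom, with 2 harmonics and without 220, 230, 240 or 260 min (exact test, adjusted p of 0.104 to 1). POX1 (limma adjusted p = 0.0017), HSP12 (0.00548) and CTT1 (0.000463) passed with 5 degrees of freedom.

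The mean of glyoxylate cycle, gluconeogenesis and acetate genes was highest at 260 and lowest at 230 min (range 3.18, 9.09-fold, all 19 members), 3 varying over all genes and 3 adjusted over the list alone (permutation adjusted p of the mean = 0.136). With each gene's mean set to 0 it was 1.25 at 260 min and 1.17 at 0 min. The highest library was 0 min for 12 members and 260 min for 2. The paralogs ACS1 and ACS2 make acetyl-CoA from acetate. ACS1 (YAL054C) had 3244 RPKM at 20 min and 20.7 RPKM at 230 min and did not pass (range 5.05 ± 1.30, adjusted p = 0.0833), and ACS2 (YLR153C) lay between 163 and 448 RPKM (range 0.45 ± 0.39, adjusted p = 0.835). Glycolysis and fermentation genes were highest at 180 and lowest at 230 min (range 2.16, 4.47-fold, 20 of 23 members), 4 varying over all genes and 4 adjusted over the list alone (permutation adjusted p = 0.195). Autophagy genes were highest at 140 and lowest at 230 min (range 1.55, 2.92-fold, all 28 members), 3 varying over all genes and 0 adjusted over the list alone (permutation adjusted p = 0.138). Hexose transporters ran from 200 to 240 min with a range of 0.89 (16 of 20 members), 2 varying over all genes and 1 adjusted over the list alone (permutation adjusted p = 0.138). With 5 degrees of freedom these 4 lists passed, with permutation adjusted p of 0.0405, 0.0279, 0.0463 and 0.0272 in the order given, and ACS1 passed as well (limma adjusted p = 0.00125). With time point number the glyoxylate and autophagy lists (permutation adjusted p = 0.0264 for both) and hexose transporters (0.0349) passed, and the glyoxylate list did without 20 min (0.0379) and with the deposited fractions (0.0489).

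Proteasome genes were highest at 60 and lowest at 230 min with a range of 0.84 (1.79-fold, SD over members 0.20, all 33 members). None varied over all genes or adjusted over the list alone by limma, fewer than in the rest (Fisher's exact test, adjusted p = 0.00268), and the mean did not pass (permutation adjusted p = 0.229). Chromatin remodelers, of interest beside the nucleosome maps of the series, had a range of 0.64 between 240 and 20 min (1.56-fold, 46 of 49 members). Of these 2 varied over all genes and 0 adjusted over the list alone (permutation adjusted p of the mean = 0.229, and 0.0282 without 0 min). Histone acetylation and deacetylation genes had a range of 0.55 between the same libraries (41 of 46 members), 2 varying over all genes and 0 adjusted over the list alone (permutation adjusted p = 0.694). Both chromatin lists held fewer varying genes than the rest (Fisher's exact test, adjusted p of 0.00564 and 0.0075). The deficits of these 2 lists and of the proteasome were lost with 3 degrees of freedom and without 220, 230 or 240 min (exact test, adjusted p of 0.409 to 1). The remodelers also lost theirs with 2 harmonics (exact test, adjusted p = 0.0766), and the acetylation list (0.0533) and the proteasome (0.125) without 210 min. Ergosterol genes had a range of 1.07 between 210 and 260 min (22 of 26 members), 10 varying over all genes and 13 adjusted over the list alone. Their mean missed the threshold (permutation adjusted p = 0.116) and passed with median-ratio scaling (0.014), quantile normalization (0.028), without 0 min (0.0334) and without 20 min (0.0241). Heme, iron and copper genes had a range of 0.39 between 0 and 230 min (23 of 30 members), 5 varying over all genes and 5 adjusted over the list alone (permutation adjusted p = 0.399). Libraries differed in scale: their median-ratio factors ran from -0.28 at 20 min to 0.21 at 240 min on the log2 scale. Under median-ratio scaling every list mean kept its direction. Quantile normalization turned the meiosis list to -0.13 and the acetylation list to -0.028, and no other list.

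Fixed pairs of lists were compared to ask whether the difference of their means followed a smooth course. Such a course can come from a difference in size as well as in timing, so a pass does not show that the peaks lay apart. Ribosome biogenesis, for one, had a range of 5.60 and cytosolic ribosomal proteins one of 3.25. Ribosome biogenesis and cytosolic ribosomal proteins differed in course: the difference of their means was highest at 220 min and lowest at 0 min, a range of 2.87 log2 units (permutation adjusted p = 0.00056). Cytosolic against mitochondrial ribosomal proteins differed most, with the difference highest at 230 and lowest at 260 min (range 5.14, permutation adjusted p = 0.0369). The other 6 pairs did not pass. DNA replication minus histones had a range of 2.96, DNA replication minus mitosis 2.14, peroxisome minus glycogen and trehalose 2.14, and mitochondrial ribosomal proteins minus the respiratory chain 1.99, all with a permutation adjusted p of 0.0881. Peroxisome minus proteasome had a range of 1.64 (permutation adjusted p = 0.126), and sulfur minus other amino acid synthesis had 0.92 (permutation adjusted p = 0.271). With 5 degrees of freedom DNA replication minus mitosis and peroxisome minus proteasome passed (permutation adjusted p = 0.00942 for both). DNA replication minus mitosis also passed with 2 harmonics (permutation adjusted p = 0.0392) and without 260 min (0.0107). Without 0 min, DNA replication minus histones passed (permutation adjusted p = 0.00251), as did mitochondrial ribosomal proteins minus the respiratory chain (0.0492, and 0.0465 without 20 min). Without 220 min, peroxisome minus glycogen and trehalose passed (permutation adjusted p = 0.0171). The first pair lost its call with 3 degrees of freedom (permutation adjusted p = 0.0744). The call on cytosolic against mitochondrial ribosomal proteins was lost there (0.08), with 2 harmonics (0.0816), and without 200, 210, 220, 230, 240 or 260 min (permutation adjusted p between 0.0624 and 0.115).

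The steps between neighbouring libraries are a description of single libraries with no test. The steps last from 10 to 50 min, and the counts are per step and not per minute. Between 240 and 260 min, 774 genes were higher and 1630 lower by at least 1 log2 unit, the most of the 11 steps: 2404 genes in 20 min, against 1372 in 10 min from 210 to 220 min. SPG1 (YGR236C), needed for survival at high temperature in stationary phase, was 6.84 log2 units higher at 260 than at 240 min. POX1 was 6.39 higher, and the acetate transporter gene ADY2 (YCR010C) was 6.27 higher. At that step the ribosome assembly genes BRX1, CGR1 and the nucleolar gene NOP13 (YNL175C) had log2 differences of -5.72, -5.49 and -5.36. The step with the fewest genes lay between 180 and 200 min, with 25 higher and 37 lower in 20 min, and 140 to 180 min had 69 and 52 in 40 min. From 0 to 20 min 336 genes were higher and 1277 lower, from 20 to 60 min 792 and 246, and from 210 to 220 min 426 and 946. The split between higher and lower depended on scaling. Under median-ratio scaling it was 1159 against 1231 at the last step, 585 against 680 from 0 to 20 min, 516 against 391 from 20 to 60 min and 692 against 661 from 210 to 220 min. From 230 to 240 min 638 genes were higher and 339 lower, or 440 and 469 with that scaling, and from 220 to 230 min 484 and 424, or 378 and 541. From 180 to 200 min the scaled split was 20 against 47. Quantile normalization gave 1123 against 1110 at the last step, 534 against 617 from 0 to 20 min, 434 against 409 from 20 to 60 min, 571 against 648 from 210 to 220 min, 489 against 461 from 230 to 240 min, and 124 against 66 from 200 to 210 min (134 against 43 unscaled).

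**Figure D3:**
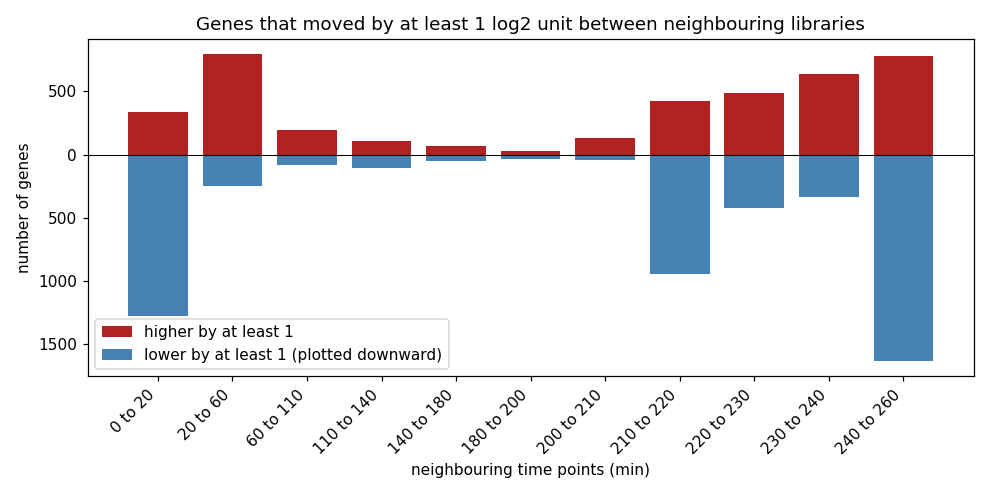
Number of genes at least 1 log2 unit higher (up) or lower (down) in the later of each pair of neighbouring libraries, by time points in minutes. The last step has 774 higher and 1630 lower genes, and the step from 180 to 200 min has 25 and 37.

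Across genes, which are not independent replicates, the Spearman correlation of the 260 min library was 0.959 with 20 min and 0.919 with 0 min. It was 0.529 with 220 min and 0.538 with 230 min. Libraries at 180 and 200 min had the highest correlation of all pairs, 0.988.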

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

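The unscaled deposited values, time point number with 5 degrees of freedom and the test on squared steps between neighbouring libraries were chosen after seeing the data. All others were planned. Peak and trough counts in this section are those of the fitted curve. In the main fit 729 of the 1342 genes peaked at 220 min and 665 were lowest at 260 min. By the highest and lowest library itself these counts were 583 and 571. With 3 degrees of freedom 145 genes varied, all 145 by at least 2-fold, 0 peaked at 220 min and 9 were lowest at 260 min, 3 lists held more varying genes than the rest and 0 pairs passed. With 5 degrees of freedom 2589 genes varied, 2570 by at least 2-fold, 1334 of them among the 1343 of the main analysis. Of the 2570, 204 peaked at 220 min and 1126 were lowest at 260 min, and 14 lists passed, 12 held more varying genes and 4 pairs passed. With that curve 1070 of the 2589 genes peaked at 230 min. Time point number gave 2657 genes, 2589 by at least 2-fold, and 11 lists, and with 5 degrees of freedom 2973 genes, 2926 by at least 2-fold, 320 peaking at 220 min, 1109 lowest at 260 min, 15 lists, among them the proteasome (permutation adjusted p = 0.00621), 12 with more varying genes, and 4 pairs. With 2 harmonics 269 peaked at 220 min. The count lowest at 260 min was 0 there, which says nothing of the data, since a curve with a period of 260 min has equal values at 0 and 260 min. Median-ratio scaling gave 8 lists past the permutation test, quantile normalization 7 with 10 holding more varying genes, and squared steps 14. Quantile normalization reversed the acetylation list (-0.028) and the meiosis list (-0.13), neither past the test. The cause was not tested for scaling, time scale or the peaks with harmonics. For the degrees of freedom a stiffer curve can leave more of a sharp change in the residual. The knots moved as well, and these effects were not told apart.

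The share of varying genes, percent of a list minus percent of the other genes, changed sign for 5 of the 12 lists past that test. With 3 degrees of freedom it was -2.26 for ribosome biogenesis, -2.24 for glycogen and -2.25 for translation factors, where 0 members varied. With 2 harmonics it was -14.8 for glycogen. For peroxisome it was 29.7 with 5 degrees of freedom, 12.6 with time point number and 28.9 with both. Leaving out libraries gave -18.1 (180 min) to 18.4 (20 min) for peroxisome, -21.4 (20 min) to 7.32 (260 min) for DNA replication, -5.22 (230 min) to 43.9 (20 min) for glycogen and -5.24 (230 min) to 42.8 (20 min) for translation factors. Ribosomal proteins, glycolysis, autophagy, stress, synthetases and ergosterol also held more varying genes with 5 degrees of freedom (exact test, adjusted p of 1.43e-49 to 0.0498), and meiosis fewer (0.0191).

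Other planned settings moved the count of varying genes by less than 1.5 times, from 962 with 2 harmonics to 1796 with quantile normalization, and the unscaled deposited values gave 1240. The rise and fall counts at the last step moved by less than 1.5 times in all settings tried, but the excess of falls did not hold. Rises and falls were 774 and 1630 in the main analysis and 1159 and 1231 with median-ratio scaling. With quantile normalization they were 1123 and 1110. Leaving out single libraries gave 277 (without 240 min) to 3309 genes (without 0 min), and 277 to 3212 by at least 2-fold. The count was 2798 without 20 min, 2097 without 60, 618 without 210, 282 without 220, 338 without 230 and 828 without 260 min. Genes peaking at 220 min ran from 5 to 1105 and those lowest at 260 min from 68 to 1265, with no value where the library itself was left out. Lists past the permutation test ran from 0, without 200, 210, 240 or 260 min, to 13 without 0 or 20 min. Lists with more varying genes ran from 3 to 15, and pairs from 1 to 4. No list mean, pair or named gene reversed when a library was left out. RPL17B, POX1, CLN3, ACS1, HSP12, SPG1 and ADY2 passed without 0 min (limma adjusted p of 0.000644 to 0.00912) and without 20 min (0.00828 to 0.0364), and HTA1 without 0 min (0.0287). Leaving out overlapping genes gave 1243 varying genes. Depth limits low genes: at 260 min 53 genes are listed at 0, and 1 read in 1 kilobase is 0.196 RPKM.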

Other observations

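The tests of gene families by symbol, of the order of the time points, of shared calls between scalings and of the 260 min library were chosen after the results were seen, while the tests of divergent against convergent and tandem neighbours were written before theirs. Outside the fixed lists, genes with the same 3 letters in their symbol were counted as families, 156 in all with at least 5 members. Each was tested for varying genes that peaked at 220 or at 260 min (312 one-sided Fisher's exact tests, of which 12 passed after adjustment). Peaks at 220 min were found for 14 of 15 TRM genes, which modify transfer RNA, 13 of 14 RRP genes of ribosomal RNA processing and 11 of 11 RPC genes of RNA polymerase subunits (Fisher's exact test, adjusted p of 4.86e-11, 2.27e-10 and 1.19e-09). The PRS genes of phosphoribosyl pyrophosphate synthesis, with 4 of 5, and the BUD genes, with 7 of 18, also passed (exact test, adjusted p of 0.0165 and 0.0336). In the other genes the share was about 10.0%. Median-ratio scaling and quantile normalization gave like counts, 14 for TRM, 12 for RRP and 11 for RPC in both. With 5 degrees of freedom the fitted peak of most of these genes lay elsewhere than 220 min (2 of TRM, 3 of RRP and 2 of RPC varied and peaked there), while the highest library was 220 or 230 min for 15 TRM, 14 RRP and 11 RPC genes. Of the PRS and BUD genes, 0 and 3 varied and peaked at 220 min with that curve. Their highest library was 220 or 230 min for 5 and 11.

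The families that passed at 260 min have names tied to the mitochondrion. They were the TOM genes (6 of 9) and TIM genes (6 of 14) of protein import, the COX genes outside the respiratory chain list (6 of 12), and COA genes (3 of 5) of cytochrome oxidase assembly (Fisher's exact test, adjusted p of 2.54e-05, 0.000542, 0.000209 and 0.0199). PET genes (5 of 16), whose mutants cannot respire, AIM genes (12 of 29), named for altered inheritance of mitochondria, and MRX genes (5 of 17) passed as well (exact test, adjusted p of 0.0151, 5.32e-08 and 0.0165). In the other genes the share was between 4.03% and 4.18%. Under both scalings and with 5 degrees of freedom each of these counts was the same or higher, and with 5 degrees of freedom 707 of all 2589 varying genes peaked at 260 min, against 316 of the 1342 that varied by at least 2-fold in the main analysis. The 260 min library was itself the highest for 6 TOM, 5 TIM, 8 COX, 1 COA, 6 PET, 16 AIM and 8 MRX genes. Symbol families are not pathways, and their members are not independent.

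For genes with a mean of at least 10 RPKM, the courses of neighbours were compared by the kind of neighbour, with random pairs as a description and no test against them. Over 12 libraries the mean correlation was 0.0776 for 19997 random pairs, 0.111 for 1366 convergent, 0.149 for 2404 tandem and 0.245 for 1299 divergent neighbours that do not overlap. Reads shared between genes that end close together would put convergent above divergent pairs, and the difference was 0.135 the other way (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3.5e-05 over 7 tests). A higher level in divergent pairs for another reason could hide some sharing there. Sharing would also raise convergent pairs at short gaps. Their mean under 300 bp minus that at wider gaps was -0.00906 (permutation adjusted p = 0.776). Convergent minus tandem pairs was -0.0385 (permutation adjusted p = 0.0499). The tests treated pairs that share a gene as independent. A promoter region shared by divergent genes is a candidate explanation, with divergent pairs 0.0960 above tandem ones (permutation p = 1e-05, adjusted p = 3.5e-05) and 0.146 higher under a gap of 300 bp than above it (permutation adjusted p = 4.67e-05). Overlapping pairs, 61 in all, had a mean of 0.766, where shared reads remain open, and genes of like function lying side by side were not tested.

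Many genes followed a smooth course. Of 100 orders of the time points, the real one included, 1 gave as many as 1343 genes, and the highest of the others gave 1247, so a chance order is argued against at 1 in 100. A constant shift of each library, such as RNA composition can leave in RPKM, is argued against as the whole cause. With median-ratio scaling, which removes such a shift, 1285 of the 1343 genes were also called. That scaling takes most genes as unchanged, so it cannot address a change in most genes or in total RNA. The high count in another order shows that some orders of these libraries are nearly as smooth as the real one.

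Ribosome biogenesis genes were lowest at 260 min. A fault of that library alone remains open. The list mean lay far from its 260 min level at 240 min (3.94 log2 units) and at 0 min (1.76 log2 units). A sharp change would look the same as a fault. Taking 0 min as next to 260 min assumes that the round repeats soon after 260 min, which was not established here. The low level was not confined to 260 min: with each gene's mean set to 0, the list mean was -2.59 at 20 min and -3.07 at 260 min. A fault had been taken to leave the 260 min library with a lower best correlation than any other library. That was not so: its best was 0.959, with 20 min, and that of the 240 min library was 0.918, with 230 min. A shift in scaling is argued against, since the median-ratio factor changed by -0.32 from 240 to 260 min and the list mean by -3.94. No biological explanation was tested.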
